A study of Mus musculus with 6 samples.

How the data were processed

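RNA from mouse adrenal glands was measured on single-colour Affymetrix arrays, with 1 biotin-labelled cRNA sample per array. Per the labels' protocols, total RNA was isolated with a guanidinium thiocyanate reagent and treated with DNase, and cRNA was prepared by the manufacturer's standard procedure. Groups were taken from the sample titles: 3 arrays of chromogranin A (Chga) knockout mice and 3 arrays of wild-type mice, all male and 12 weeks old. The series describes 3 mice per group, so that each array was read as 1 animal.

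The deposited values are linear array intensities, 1 per probe set, made by the authors with MAS5 per the submitters' processing notes. Its version and scaling target are not given in the sources used here, and no detection calls were used. The mean signal after removing the highest and lowest 2% of probe sets was 2501 on each of the 6 arrays, so the values were already scaled to a common target and were not normalized again. Each array held 12488 probe sets, of which 66 control probe sets were left out of the tests. Of the other 12422, 10833 had 1 gene symbol in the platform annotation, 396 had several and 1193 were not listed there. Probe sets without a single symbol were tested but not named. Symbols were updated through the Entrez identifier with a RefSeq gene table of the GRCm38 assembly, in which 16 probe sets had no match. That table was used only for names and for the order of genes along a chromosome. The files name no genome build, and no coordinates are given.

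Values were transformed as log2(signal + 16). Probe sets whose mean log2 signal over the 6 arrays lay under the 40th percentile, equal to a signal of about 582, were left out, which kept 7453 probe sets of 5663 named genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all tested probe sets and a threshold of 0.05. Every adjusted p given for a gene is from this test. Fold changes are on the log2(signal + 16) scale, which understates the change of dim genes. Errors of signals are SD over n = 3 arrays and errors of log2 changes are standard errors. Precision was judged from the spread over arrays, since an array gives no counting depth.

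For gene lists, each gene was represented by its tested probe set of highest mean. The 34 lists were fixed before the data were examined. They covered granins and prohormone processing, secretory vesicle exocytosis, catecholamine synthesis, chromaffin cell identity, chromaffin neuropeptides, medullary receptors and channels, steroidogenesis, the renin-angiotensin-aldosterone axis with the zona glomerulosa, the foetal X zone, cholesterol biosynthesis and uptake, immediate early genes, glucocorticoid responsive genes, the unfolded protein response, heat shock chaperones, antioxidant genes, oxidative phosphorylation, ribosomal proteins, glycolysis, fatty acid oxidation, cell cycle, interferon stimulated genes and major histocompatibility genes. Marker lists covered adipocytes, lymphocytes, macrophages, erythroid cells, endothelium, capsule fibroblasts, smooth muscle, Schwann cells, skeletal muscle, liver, kidney and sex. Lists with at least 5 tested genes were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 30 lists tested. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance without reference to other genes, were run as alternatives. Counts of list members past the threshold are also given adjusted over the list alone. Genes next to Chga were the 25 tested genes on either side of it, and their share with an unadjusted p under 0.05 was compared with that of all other genes by a two-sided Fisher's exact test.

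The genes named were chosen by a rule fixed before the data were examined: Chga and other granin list members; up to 15 higher and 15 lower genes of largest change among those past the threshold whose 3 knockout arrays all lay on one side of the 3 wild-type arrays, by the brightest probe set of each gene, with a direction of fewer than 10 genes filled up to 10; and up to 4 members of each list with the smallest unadjusted p. Other genes named were chosen after their values were seen, which holds for Th, Pnmt, Cyp21a1, Ier2, Sc5d, Idi1, Lss, Ahcy, AI506816, the muscle transcripts Myh1, Tnnt3 and Mb, and the members of the neighbour and additional lists. It also holds for Thrb and for the adipocyte markers other than Cidec, Adipoq, Lep and Orm1.

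Alternatives fixed beforehand were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile, cyclic loess and median scaling, eBayes without trend and robust, array weights, the replicate number as a block, each array left out, a plain unmoderated test, other thresholds, other list tests and other neighbour windows. Chosen after seeing the data were a covariate for the 3' to 5' signal ratio of control probe sets, a covariate for skeletal muscle transcripts, and knockout array 1 alone against the wild-type arrays. That last fit holds 1 knockout array, so its p-values and calls take their spread from the wild-type arrays and cannot speak for the genotype. The limma and camera steps were tested on simulated data of 7453 probe sets on 3 against 3 arrays with 200 changed probe sets in each of 20 draws. They recovered 64.9% of 2-fold and 96.0% of 4-fold changes, with 5.16% false among the calls. The simulated noise was normal with the moderated variances of the fit, and no draw held a difference in RNA quality or tissue. These shares therefore need not hold for the real data. A shifted list was found in 20 of 20 draws, and 1 of 580 lists without a shift was called. The simulated probe sets varied independently, so these draws do not show how often camera calls lists of correlated genes. In the real data the estimated correlation was 0.24 in the cholesterol list and 0.26 in the cell cycle list.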

Results

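The adrenal gland joins a steroid-producing cortex to a medulla of chromaffin cells, which store catecholamines in granules together with chromogranin A, the product of Chga. The series set the adrenal glands of Chga knockout mice beside those of wild-type mice, which addresses how adrenal gene expression differs without this granule protein. There were 3 arrays per genotype, each read as 1 male mouse of 12 weeks. The median signal lay between 953 and 1092 on the 6 arrays. Signals of 2 arrays correlated across probe sets with r between 0.910 and 0.956, where probe sets are not independent replicates.

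Chga itself was nearly lost from the knockout glands. Its brighter probe set gave 37413 ± 8452 (SD, n = 3) in wild-type and 999 ± 170 (SD, n = 3) in knockout adrenals, a 36.6-fold decrease (log2 change -5.19 ± 0.20, limma adjusted p = 5.29e-06). The other probe set gave 9161 ± 920 and 83.4 ± 31.8 (SD, n = 3 each), a decrease of roughly 95.1-fold (adjusted p = 8.66e-06). The size of this second decrease depends on the pseudocount, since the knockout signal was dim: the log2 change was -6.57 ± 0.28, and -6.82 and -5.98 with pseudocounts of 1 and 64. Both probe sets separated all 3 knockout from all 3 wild-type arrays, as the labels state. Whether either lies in the deleted part of the gene was not analysed here. The 999 left on the brighter probe set was close to the median signal of an array.

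Beyond Chga, genes switched on early by stimuli were higher in the knockout adrenal, and genes of cholesterol synthesis were lower. Over all 7453 probe sets tested, 33 passed the threshold, 12 higher and 21 lower in the knockout. They stood for 24 named genes, 10 higher and 14 lower, and 4 lower probe sets that have no single gene name here. At an unadjusted p under 0.05 there were 843 probe sets, 377 higher and 466 lower. The ratio of 3' to 5' signal of control transcripts, a sign of RNA or cRNA integrity, differed between the genotypes: for Gapdh it was 1.14 ± 0.27 in knockout and 0.787 ± 0.023 in wild-type arrays (SD, n = 3), and all 3 knockout arrays exceeded all wild-type arrays. Knockout arrays 2 and 3 had the highest ratios and also carried skeletal muscle transcripts. With knockout array 1 alone against the 3 wild-type arrays, chosen after seeing the data, 13 probe sets passed, 11 of them among the 33. Leaving out knockout array 1 raised the count to 141, while leaving out knockout array 3, wild-type array 2 or wild-type array 3 lowered it to 15, 17 and 19.

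**Figure D1:**
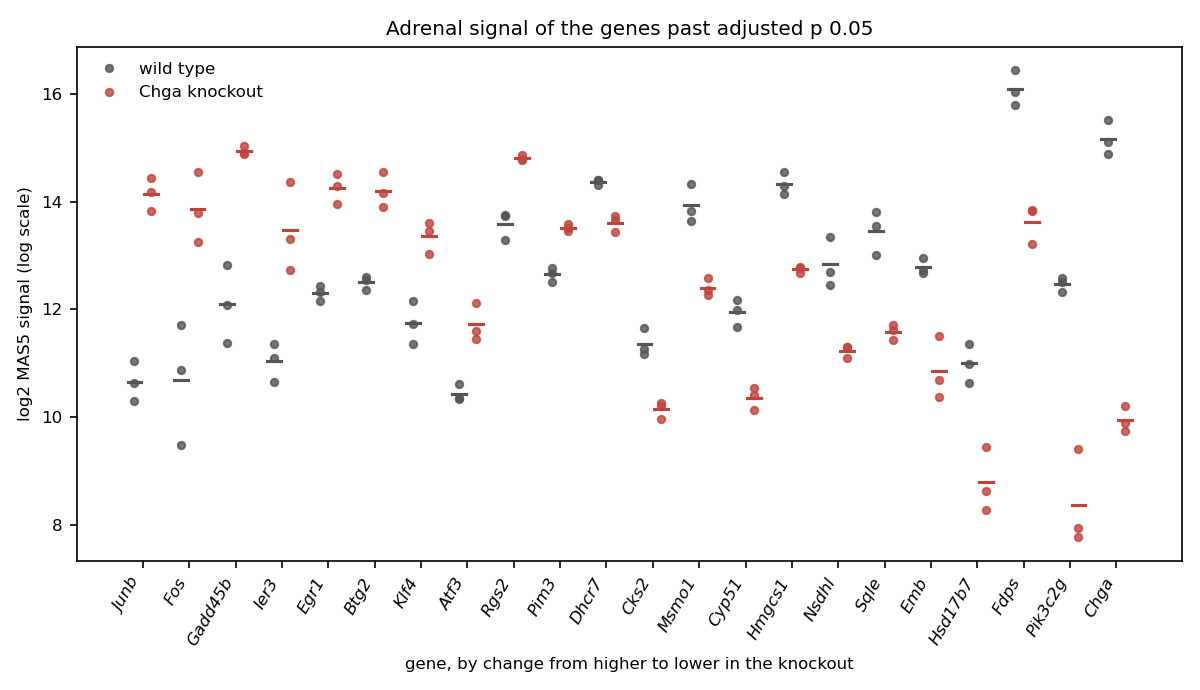
Signal on a log2 axis of the 22 genes named by size, with 1 point per array, wild type in grey and Chga knockout in red, and a bar at the mean of the 3 log2 signals. Genes run from the largest increase (Junb, log2 change 3.48) to the largest decrease (Chga, -5.19), and in each gene the 3 knockout points lie on one side of the 3 wild-type points, as the rule for naming required.

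Immediate early genes, which cells transcribe within minutes of a stimulus, were the main group that was higher. Junb, a subunit of the AP-1 transcription factor, rose 11.1-fold, from 1652 ± 428 to 18405 ± 3758 (SD, n = 3, adjusted p = 0.000139), and its second probe set rose by 4.68 ± 0.27 on the log2 scale. Fos, its AP-1 partner, rose 8.89-fold (adjusted p = 0.0403) and the zinc finger factor Egr1 rose 3.84-fold, from 5077 ± 465 to 19728 ± 3770 (SD, n = 3, adjusted p = 0.000861). Ier3, Btg2, Klf4 and Atf3 rose by 2.42, 1.69, 1.61 and 1.27 on the log2 scale. Of 24 list members tested, 7 rose and 17 did not pass, and 16 rose when adjusted over the list alone. Among those that did not pass over all genes, Nr4a2 had a log2 change of 1.97 (adjusted p = 0.0676), Dusp1 1.28 (0.0732) and Ier2 0.99 (0.0602). The list had a median log2 change of 0.99 and its shift passed (camera adjusted p = 6.61e-19, and adjusted p = 0.0479 with an estimated correlation). The median was 1.12 with knockout array 1 alone. Without knockout array 2, without knockout array 3 or without wild-type array 2, the call of Fos was lost, and Klf4, Ier3 and Atf3 kept their calls in 3, 2 and 1 of the 6 fits that left out an array.

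3 more genes outside that list were higher. Gadd45b, a stress-inducible gene of the growth arrest family, rose 7.15-fold (adjusted p = 0.00309) and by 2.29 on the log2 scale on a second probe set. Rgs2, which dampens G protein signalling, rose 2.33-fold, from 12450 ± 2173 to 28757 ± 993 (SD, n = 3, adjusted p = 0.00948), a call that was lost without knockout array 3. The kinase gene Pim3 rose 1.82-fold (adjusted p = 0.0317), a call that was lost in 4 of the 6 fits that left out an array.

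8 genes of cholesterol biosynthesis, from early to late steps of the pathway, were lower in the knockout adrenal. Fdps, which makes farnesyl diphosphate, fell from 70826 ± 16318 to 12904 ± 2943 (SD, n = 3), a 5.49-fold decrease (log2 change -2.46 ± 0.21, adjusted p = 0.000861). Hmgcs1, at the head of the mevalonate pathway, fell 2.98-fold, from 20607 ± 3000 to 6856 ± 289 (SD, n = 3, adjusted p = 0.000991), and the squalene epoxidase gene Sqle fell 3.65-fold (adjusted p = 0.0043). The genes of later sterol enzymes, Hsd17b7, Nsdhl, Cyp51, Msmo1 and Dhcr7, fell 4.49-fold, 3.02-fold, 2.97-fold, 2.88-fold and 1.69-fold. Of 18 list members tested, 8 fell, none rose and 10 did not pass, and 14 fell when adjusted over the list alone. Idi1 had a log2 change of -2.18 (adjusted p = 0.113), Lss -1.61 (0.167) and Sc5d -1.50 (0.0785), none past the threshold.

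The cholesterol list had a median log2 change of -1.51, and 16 of its 18 values were lower. Its shift passed with the preset correlation (camera adjusted p = 2.85e-19) but not with an estimated one (adjusted p = 0.164 with an estimated correlation), while fry gave an adjusted p of 0.0183. The median was -1.43 with knockout array 1 alone. Fdps and Egr1 were also called with knockout array 1 alone, as were Junb, Ier3 and Pik3c2g, while the other 18 named genes with a call besides Chga were not. Msmo1, Cyp51, Nsdhl, Hsd17b7 and Dhcr7 kept their calls in 5, 4, 3, 2 and 1 of the 6 fits that left out an array.

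Other genes fell outside these pathways. Pik3c2g, which encodes a class II phosphoinositide 3-kinase and belonged to the foetal X zone list, fell 16.3-fold, from 5687 ± 514 to 382 ± 260 (SD, n = 3, adjusted p = 0.00149). The other X zone genes tested, Nr2f2 and Cdh1, had log2 changes of -0.13 and 0.00, and with 3 genes the list was not tested as a whole. Thrb, also on that list, was left out as dim. Its signal was 859, 180 and 238 on knockout arrays 1 to 3 and 812, 1211 and 962 on the wild-type arrays. Emb, which encodes the cell surface protein embigin, fell 3.80-fold (adjusted p = 0.0178), a call that was lost without knockout array 3, wild-type array 2 or wild-type array 3. Ahcy, the S-adenosylhomocysteine hydrolase gene, fell 2.24-fold on 1 probe set (adjusted p = 0.0391), but its brightest probe set, with a log2 change of -0.79, did not pass (adjusted p = 0.403). The unassigned transcript AI506816 fell 3.48-fold on 1 probe set (adjusted p = 0.0317), and its brightest probe set did not pass either (adjusted p = 0.484). Ahcy kept its call in 2 and AI506816 in 1 of the 6 fits that left out an array.

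Cell cycle transcripts had lower values as a group. Cks2, a partner of cyclin-dependent kinases, fell 2.30-fold, from 2662 ± 484 to 1139 ± 120 (SD, n = 3, adjusted p = 0.045), a call kept in 1 of the 6 fits that left out an array. The other 22 members tested did not pass, and 13 fell when adjusted over the list alone. The nucleotide reductase subunit Rrm2 had a log2 change of -1.55 (adjusted p = 0.129), the microtubule regulator Stmn1 -0.93 (0.155) and the replication helicase subunit Mcm4 -0.96 (0.166). The list median was -0.70 (camera adjusted p = 8.76e-11, and adjusted p = 0.322 with an estimated correlation). It was -0.94 with knockout array 1 alone.

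In the chromaffin cells' own gene groups, Chga fell and no other list member tested passed over all genes. Of the 15 granin and processing genes tested, Chga fell and 14 did not pass; adjusted over the list alone, 2 rose and 1 fell. Chgb, the related granin, had 74187 ± 4257 in wild-type and 103998 ± 14220 in knockout arrays (SD, n = 3, log2 change 0.48, adjusted p = 0.23). Pcsk1n, which encodes a prohormone convertase inhibitor, had a log2 change of 1.02 (adjusted p = 0.206) and Scg2 one of 0.15. Pam, the amidating enzyme, read 402 on knockout array 1 and 4968 and 4249 on the others, against 5856 ± 114 in wild type (SD, n = 3, adjusted p = 0.504). The list's median was 0.16 and its mean -0.24, and the test leaned upward (camera adjusted p = 0.338).

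Genes that make, store or break down catecholamines did not pass the test. Of 9 tested in limma, 0 passed over all genes, 0 passed when adjusted over the list alone and 0 had an unadjusted p under 0.05. Th, the first enzyme of the pathway, had a log2 change of 0.12 and Pnmt, which makes adrenaline, one of -0.23, and the largest value was that of Gch1, at -0.59. The list's median was 0.15 (camera adjusted p = 0.63). The values of Th, Pnmt and Gch1 changed sign with the 3' to 5' ratio as a covariate. Among vesicle exocytosis genes, 0 of 14 passed, and 1 rose and 1 fell when adjusted over the list alone (Vamp2 0.57, Dnajc5 -1.07 on the log2 scale, camera adjusted p = 0.516). Among medullary receptors and channels 0 of 7 passed, and 2 calcium and potassium channel genes rose when adjusted over the list alone, Cacna1c (0.65) and Kcnma1 (0.67), with a list adjusted p of 0.144.

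2 chromaffin lists had higher values as groups. Of 7 neuropeptide genes none passed over all genes and 2 rose when adjusted over the list alone: the enkephalin precursor Penk had 5157 ± 1076 in wild-type and 11107 ± 2345 in knockout arrays (SD, n = 3, adjusted p = 0.0785), and neuropeptide Y, Npy, had a log2 change of 0.78 (adjusted p = 0.269). The list's median was 0.26 (camera adjusted p = 0.0115, and adjusted p = 0.358 with an estimated correlation). It did not pass with knockout array 1 alone (adjusted p = 0.240), where the median was 0.38, or without knockout array 3 (0.127), where it was 0.22. Of 11 chromaffin identity genes 0 passed, over all genes or adjusted over the list alone, and 9 had higher values, such as the transcription factor gene Gata2 (0.51) and Dlk1 (0.38). That list's median was 0.29 (camera adjusted p = 0.0144, and adjusted p = 0.358 with an estimated correlation). Without knockout array 1, wild-type array 2 or wild-type array 3 it did not pass (0.0857, 0.162 and 0.0560), with medians of 0.37, 0.22 and 0.27.

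The steroid-producing machinery of the cortex showed no call. Of 18 steroidogenesis genes tested, 0 passed, also when adjusted over the list alone. Cyp21a1, the 21-hydroxylase, had a log2 change of 0.24, and Nr0b1, a repressor of steroidogenic genes, one of -0.75 (adjusted p = 0.32). The list's median was 0.09 (camera adjusted p = 0.329). Of 12 genes of the renin-angiotensin-aldosterone axis and zona glomerulosa 0 passed, and 2 rose when adjusted over the list alone, Nr4a2 and Nr4a1 (1.05), which were also in the immediate early list. Its median was -0.03 and its mean 0.19, with an upward lean in the test (camera adjusted p = 0.348). Glucocorticoid responsive genes had a median of 0.30, with 16 of 17 values higher (camera adjusted p = 0.000646, and adjusted p = 0.186 with an estimated correlation). None of them passed over all genes and 2 rose when adjusted over the list alone, Dusp1, shared with the immediate early list, and Ddit4 (1.02). The list's median was 0.43 with knockout array 1 alone.

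**Figure D2:**
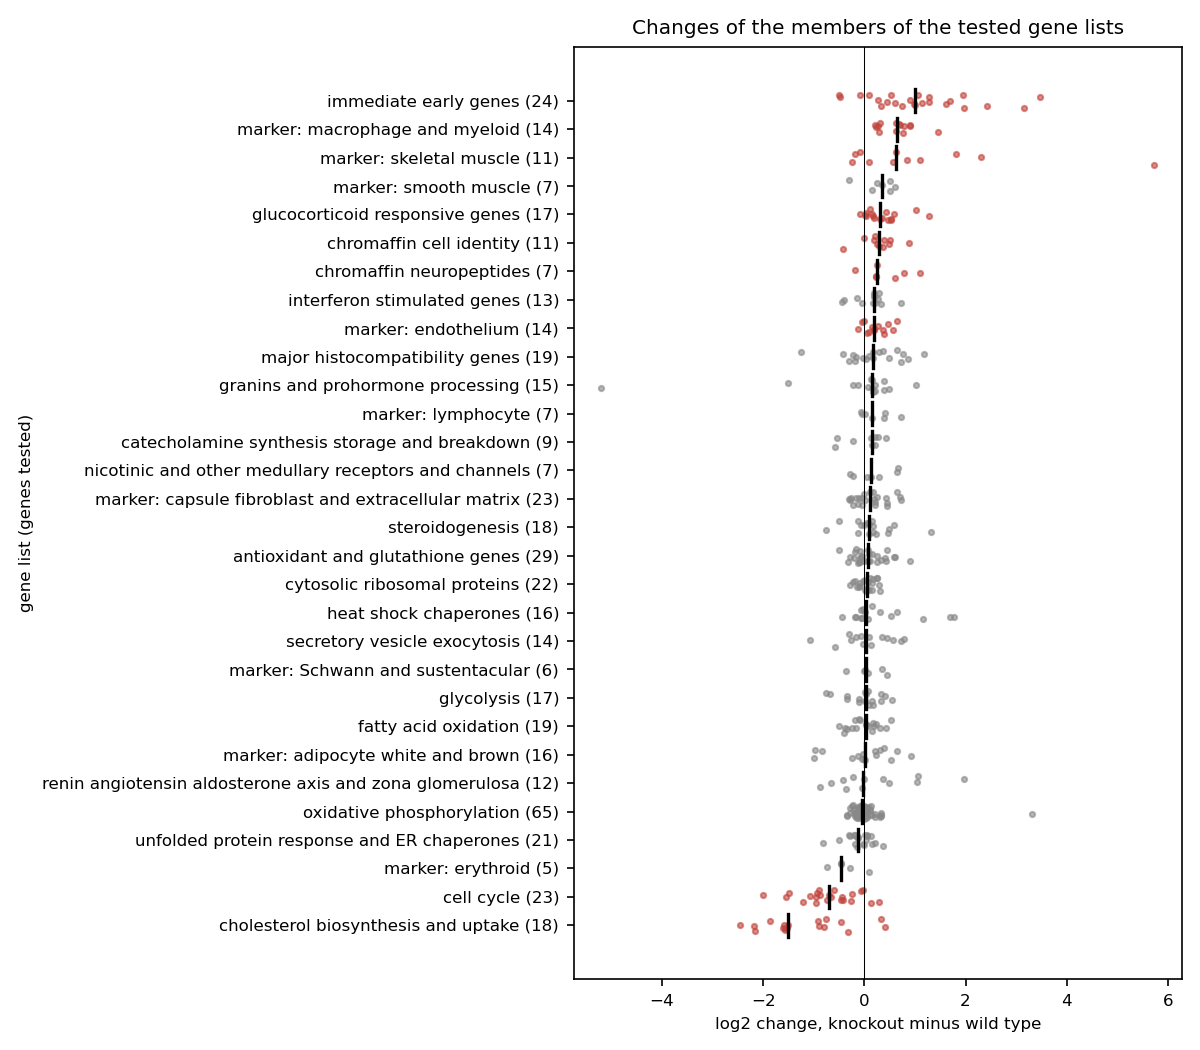
Log2 change, knockout minus wild type, of each tested member (points) of the 30 lists tested, with a black bar at the list median and the number of genes tested in brackets; points are spread vertically for visibility, and red lists passed camera with the preset correlation. The cholesterol list has the lowest median (-1.51) and the immediate early list the highest (0.99), while granin genes centre on 0.16 with Chga at -5.19.

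Markers of macrophages and endothelium had higher values as groups. Macrophage and myeloid genes had a median of 0.65, with all 14 values higher, such as the receptor gene Csf1r (0.91, adjusted p = 0.186) and Mpeg1 (0.90). The list passed camera (adjusted p = 2.18e-05) but not with an estimated correlation (adjusted p = 0.358 with an estimated correlation). 0 members passed over all genes and 1 rose when adjusted over the list alone. The median was 0.01 with knockout array 1 alone, the knockout array with the lowest 3' to 5' ratios, and the list did not pass (adjusted p = 0.435). Endothelial genes had a median of 0.19 (camera adjusted p = 0.0334, and adjusted p = 0.358 with an estimated correlation), with 0 of 14 past the threshold, and Eng at 0.47. The list did not pass with knockout array 1 alone (adjusted p = 0.199), where its median was still 0.14. It also did not pass without knockout array 2, wild-type array 2 or wild-type array 3 (0.101, 0.162 and 0.0616), with medians of 0.27, 0.11 and 0.20.

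Skeletal muscle transcripts were high on 2 knockout arrays. Acta1, skeletal muscle actin, read 565, 32131 and 13869 on knockout arrays 1 to 3 and 180, 180 and 29.1 on the wild-type arrays (log2 change 5.73 ± 1.28, adjusted p = 0.153). Myh1, a myosin heavy chain gene, read 163, 10290 and 4516 against 115, 62.6 and 157. The list's median was 0.62 (camera adjusted p = 0.0108, and adjusted p = 0.532 with an estimated correlation). 0 of 11 members passed over all genes, 1 rose when adjusted over the list alone, and Atp2a1 had a value of 2.31. Without knockout array 2 or knockout array 3 the list did not pass (adjusted p = 0.151 and 0.246), with medians of 0.11 and 0.55, and without knockout array 1 its median was 1.31.

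**Figure D3:**
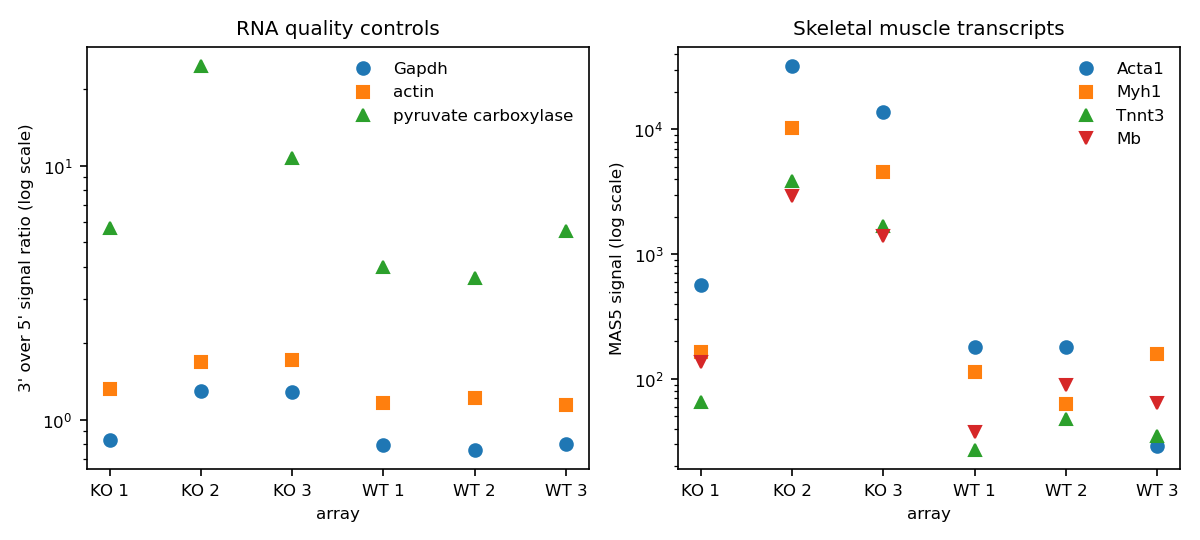
Left, ratio of 3' to 5' signal of 3 control transcripts on each of the 6 arrays, on a log axis; right, signal of 4 skeletal muscle transcripts on the same arrays, on a log axis. Knockout arrays 2 and 3 have the highest ratios (24.7 and 10.8 for pyruvate carboxylase) and the highest muscle signals (Acta1 32131 and 13869).

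No other marker list passed. Median log2 changes and camera adjusted p values were 0.00 and 0.516 for adipocytes, 0.16 and 0.329 for lymphocytes, 0.10 and 0.329 for capsule fibroblasts, 0.34 and 0.0997 for smooth muscle, 0.04 and 0.614 for Schwann cells and -0.45 and 0.144 for erythroid cells, whose Hbb-b2 had a value of -0.74. Adjusted over the list alone, 1 fibroblast gene rose, Dcn (0.73, adjusted p = 0.0660 over all genes). Liver, kidney and sex lists had 3, 2 and 1 tested genes, with medians of 0.36, 0.42 and 0.02, and were not tested. The liver marker Alb read 504, 2909 and 2811 on knockout arrays 1 to 3 and 709, 678 and 832 on the wild-type arrays (adjusted p = 0.508). The other liver genes, Cyp2e1 and Cps1, had values of 0.36 and -0.22. In limma 0 members of these lists passed over all genes.

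General stress and metabolic lists did not pass as groups either. Heat shock chaperones had a median of 0.04 (camera adjusted p = 0.144), yet 3 of 16 rose when adjusted over the list alone, among them the inducible Hsp70 genes Hspa1b (1.69, adjusted p = 0.0602 over all genes) and Hspa1a (1.77, 0.155), which are near-identical copies that probe sets may not tell apart. The median and camera adjusted p were -0.12 and 0.338 for the unfolded protein response, 0.07 and 0.391 for antioxidant genes, 0.04 and 0.39 for ribosomal proteins, 0.20 and 0.365 for interferon stimulated genes and 0.17 and 0.329 for major histocompatibility genes. Oxidative phosphorylation (-0.04, with a mean of 0.02 and a downward lean, 0.516), fatty acid oxidation (0.02, with a mean of -0.01 and a downward lean, 0.87) and glycolysis (0.03, with a mean of -0.01 and an upward lean, 0.87) had medians and means of different sign. The hexokinase gene Hk2 fell when adjusted over the glycolysis list alone (-0.76, adjusted p = 0.167 over all genes).

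Genes next to Chga on its chromosome were compared with all others, since a targeted allele can carry neighbouring DNA of another strain. Of the 50 neighbours, 10 (20%) had an unadjusted p under 0.05, against 597 of 5612 other genes (10.6%), an odds ratio of 2.10 (95% interval 0.93 to 4.30, Fisher's exact p = 0.0604). Fos lay among them, 19 tested genes away from Chga, and was the only neighbour past the threshold over all genes. The other 9 were 6 with higher and 3 with lower values. Among the higher were Dync1h1 (log2 change 0.64), Dlk1 (0.38) and Itpk1 (0.48), which lies next to Chga among tested genes. Serpina1b (1.15) and Serpina1c (0.83) were also higher, and belong to a multigene family whose copies a probe set may share. Both were highest on knockout arrays 2 and 3, as was the liver marker Alb, while Dync1h1 and Itpk1 were highest on knockout array 1. Whether RNA of another tissue raised the count of neighbours was not tested. The lower ones were Psmc1 (-0.44), Cpsf2 (-0.50) and Papola (-0.62). With 10 genes on either side the exact p was 0.0553 and with 50 it was 0.403. At an unadjusted p under 0.01 there were 3 of the 50 neighbours against 175 of 5612 other genes (exact p = 0.207). The comparison passed without wild-type array 1 (0.00271) or wild-type array 3 (0.0401), with median scaling (0.00501) and without the eBayes trend (0.0288). It did not pass with knockout array 1 alone (exact p = 0.740). Limma's fry, which does not compare the neighbours with other genes, passed a threshold of 0.05 both for a shift one way and for changes in either direction.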

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

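The tests on the immediate early, cholesterol and muscle patterns were chosen only after these results were seen; those of other splits of the arrays were chosen before.

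Control probe sets outside the main comparison read the 3' and 5' ends of the same transcript, and their ratio was higher on all 3 knockout arrays than on all 3 wild-type arrays for each of 3 controls. The knockout ratio was 1.42 times that of wild type for Gapdh, 1.33 times for actin and 2.66 times for pyruvate carboxylase (geometric means). For pyruvate carboxylase it was 13.7 ± 9.8 and 4.39 ± 1.03 (SD, n = 3). The exact permutation p was 0.10 for each, the smallest that 3 against 3 arrays allow.

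The immediate early genes were higher in the knockout by a list mean of 1.08 on the log2 scale. With the 3' to 5' index as a covariate this was 1.23 (95% interval 0.74 to 1.71). With the index of muscle transcripts it was 1.20 (0.79 to 1.61). Both intervals lay wholly above 0.5 of the uncorrected shift. Both indices were highest on knockout arrays 2 and 3, so the fits are not separate evidence and rest mainly on knockout array 1. The muscle index of that array (10.1) lay among those of wild type (9.97 to 10.2), which argues against muscle tissue as the main cause. The 3' to 5' index, a mean log2 ratio of the 3 controls, was higher on every knockout array than on every wild-type array. On knockout array 1 it was 0.88, against 0.58 to 0.79 in wild type and 1.92 and 1.53 on knockout arrays 2 and 3. The list median was 1.12 with knockout array 1 alone. With 1 such array, and no overlap between genotypes, RNA quality cannot be separated from genotype. The 3' to 5' correction turned the median of the muscle list to -0.24, which is no check on it, since the indices rose together. Handling before the tissue was frozen could also raise these genes, and cannot be told apart from genotype, since 0 of the 6 samples have a label for collection day, order or litter. An effect of the knockout itself stays open in the same way.

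The cholesterol biosynthesis genes were lower by a list mean of -1.19. Under quantile, cyclic loess and median scaling the mean nearest 0 was -1.17, which argues against scaling. With the 3' to 5' index the mean was -1.26 (95% interval -2.22 to -0.30), and with the muscle index -1.23 (-2.07 to -0.39). Whether either accounts for over 50% of the shift cannot be told apart on 6 arrays, because the intervals are wide. By a second criterion, chosen afterwards, the bounds nearest 0 were -0.30 and -0.39. The 3' to 5' index was higher on every knockout array than on every wild-type array. On knockout array 1 it was 0.88, against 0.58 to 0.79 in wild type, and the list median with that array alone was -1.43. The 3' to 5' fit cannot separate RNA quality from genotype, so RNA quality stays open. The muscle index of knockout array 1 (10.1) lay among those of wild type (9.97 to 10.2). The bound of -0.39 argues against muscle as the whole cause, but rests mainly on that array. A knockout effect, diet or feeding state stay open and were not tested.

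Skeletal muscle transcripts differed between arrays of one genotype: of the 24 probe sets of the muscle list, dim ones included, 70.8% were brightest on one pair of arrays, knockout arrays 2 and 3, the highest share over the 15 pairs; the highest among other probe sets was 13.9%, for another pair. In 10000 random sets of 24 other probe sets no pair held over 41.7%, so that the permutation p was 0.0001, the smallest they can give, and probe sets are not independent. This is consistent with muscle tissue in some of the samples, a source that no sort or gate would have removed. Acta1 reached 32131, Myh1 10290 and Tnnt3 3856 on knockout array 2, and 11 of the list's 16 genes passed the filter on dim probe sets. A biological explanation was not tested.

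Splits of the 6 arrays into 3 and 3 are too few, at 10, for a share under 0.05. The real split gave 33 probe sets past the threshold and the highest other split 0, so that 1 of 10 splits gave as many. For gene lists the real split gave 9 and the highest other 11, and 4 splits gave as many or more. For the neighbours of Chga the real split gave 10 and the highest other 10, so that 2 splits gave as many.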

How the results depend on the processing

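The covariate fits and knockout array 1 alone were chosen only after the results were seen; the other alternatives were fixed before. Where no reason is given, the cause of a change was not tested. Chga fell in every fit on its brighter probe set (log2 change -4.87 to -5.34). The other probe set fell in each fit that tested it (-5.98 to -6.82), and was left out as dim at the 60th percentile, without wild-type array 1 and without wild-type array 3. At the 60th percentile neuropeptides, skeletal muscle, receptors and channels, lymphocytes and Schwann cells kept too few genes for a test. The immediate early list passed in every alternative run, with an adjusted p of at most 0.0479. The 33 probe sets past the threshold became 17 without the eBayes trend, 55 at an adjusted p of 0.1, and 0 in the plain unmoderated test at an adjusted p of 0.05. They became 9 with the 3' to 5' index (8 of the 33), 21 with the muscle index (15 of the 33) and 13 with knockout array 1 alone, a fit in which that array is assumed to vary like the wild-type arrays. Without 1 array the count ran from 15 to 141. Of 23 named genes with a call besides Chga, 2 kept it with the 3' to 5' index, 9 with the muscle index and 5 with knockout array 1 alone. All 23 had their direction with either index. The ratio of a gene's change to that with 6 arrays and no covariate had a median of 1.01 (0.60 to 1.45), 1.03 (0.66 to 1.40) and 1.03 (0.67 to 1.37), so that some changes shrank and others grew, while standard errors were larger (median ratio 1.59, 1.41 and 1.39). Fdps went from -2.46 ± 0.21 to -2.35 ± 0.35 with the 3' to 5' index (adjusted p = 0.0809). Junb kept its call in all 20 limma alternatives at the 0.05 threshold. In the plain unmoderated test it was not called, and neither was any other probe set, those of Chga included. Without the filter on dim probe sets, which adds those of low signal over background, 15 of the 23 kept their call.

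With the replicate number as a block the calls were 57, of which 32 were among the 33, and the neighbours of Chga passed (exact p = 0.0491). The deviations of arrays with the same number from their group means had r = 0.26, -0.04 and -0.04 across probe sets, which does not show that the numbers pair the samples. Arrays 1 correlated best with each other, while knockout arrays 2 and 3 correlated best with wild-type arrays 3 and 2 (0.25 and 0.16).

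With an estimated correlation 1 list passed and with fry 2, against 9. The adjusted p was, with an estimated correlation and fry in turn, 0.322 and 0.126 for cell cycle, 0.186 and 0.0774 for glucocorticoid genes, 0.532 and 0.540 for skeletal muscle, and 0.358 and 0.211 for macrophages, neuropeptides, chromaffin identity and endothelium; for cholesterol it was 0.164 with an estimated correlation. Chromaffin identity was at 0.0814 without the filter and 0.057 at the 60th percentile, where endothelium was at 0.104. With the 3' to 5' index, muscle index and knockout array 1 alone in turn, macrophages were at 0.695 (turned lower), 0.426 and 0.435, neuropeptides at 0.134, 0.145 and 0.240 (medians 0.44, 0.40 and 0.38, against 0.26), endothelium at 0.441, 0.209 and 0.199 (medians 0.07, 0.17 and 0.14, against 0.19), and skeletal muscle, turned lower, at 0.134, 0.733 and 0.240. Leaving out 1 array gave 4.56e-08 to 0.246 for skeletal muscle, 0.0059 to 0.127 for neuropeptides, 0.00164 to 0.162 for chromaffin identity and 0.00607 to 0.162 for endothelium.

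Lists without a call turned direction, in the same order of settings, in these cases: unfolded protein response (0.0249, past the threshold, 0.145, 0.0947), interferon (0.157, 0.352, 0.245), histocompatibility (0.134, 0.475, 0.240), adipocytes (0.00137, past the threshold, 0.0961, 0.0728), fibroblasts (0.00524, past the threshold, 0.335, 0.228) and fatty acid oxidation (0.408, 0.209, 0.102). Heat shock (0.911) and smooth muscle (0.911) turned with the 3' to 5' index, oxidative phosphorylation (0.750, 0.419) and granins (0.737, 0.900) with the other 2 settings, and granins with fry (0.633). Exocytosis turned at the 60th percentile (0.946), ribosomal proteins with quantile scaling (0.854), glycolysis without the filter (0.986), with quantile (0.955) and with loess (0.973), and fatty acid oxidation with all probe sets averaged (0.970). Ribosomal proteins passed at 0.00743, 0.021 and 0.00371 in the 3 added settings, erythroid genes at 0.0488 with the 3' to 5' index and the aldosterone axis at 0.0329 at the 60th percentile.

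Leaving out 1 array gave 0.0267 to 0.444 for receptors and channels (past without knockout array 2 or wild-type array 2), 6.44e-05 to 0.426 for erythroid genes (without wild-type array 1) and 0.0255 to 0.834 for fibroblasts (without knockout array 1 or wild-type array 3). Without knockout array 1 these passed: unfolded protein response (0.0206 to 0.925), interferon (0.0266 to 0.780), histocompatibility (0.0266 to 0.702) and smooth muscle (0.0255 to 0.246). Without wild-type array 1 the unfolded protein response turned higher (0.925). Some fits turned oxidative phosphorylation (0.123 to 0.895), ribosomal proteins (0.106 to 0.902), glycolysis (0.335 to 0.902), fatty acid oxidation (0.260 to 0.894), adipocytes (0.114 to 0.627) and Schwann cells (0.426 to 0.894). The neighbours of Chga gave an exact p of 0.00271 to 0.245, 0.00501 with median scaling and 0.0288 without the trend.

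Genes turned with the 3' to 5' index, muscle index and knockout array 1 alone: Th at -0.0070, -0.0031 and -0.026, and Pnmt at 0.26, 0.14 and 0.15. With the 3' to 5' index Gch1 was at 0.17 and Atp2a1 at -0.49. None of the 4 had a call. The median change of all genes moved by under 0.1 under each scaling (-0.003 to 0.015).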

Other observations

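The clock, LXR and SREBP1 lists were added after the main results were seen, while their tests were fixed before these lists were examined.

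Genes of lipid synthesis outside the cholesterol pathway had values of both signs. Among 10 fatty acid synthesis genes, only Scd1 and Elovl6 had higher values (log2 changes of 0.19 and 0.42), and the list median was -0.07. Of the lower ones, Gpam had a log2 change of -0.53 (adjusted p = 0.27), Acly -0.25 and Fasn -0.09. Scd1 ranged from 3788 to 66940 within the knockout arrays. Within each genotype Scd1 and Fasn were lowest on array 1. So were the adipocyte markers Adipoq, Orm1, Retn, Ucp1, Lpl, Car3, Thrsp, Pck1 and Fabp5, and Dgat1 on its brighter probe set only. This did not hold for the tested markers Cidec, Lep, Fabp4, Cox8b, Cidea and Pparg. Whether attached fat adds to the signal of Scd1, Fasn or the markers lowest on array 1 was not tested. Among 5 sterol-induced genes of the nuclear receptor LXR, the cholesterol exporter gene Abca1 had a log2 change of -0.46 and Pltp one of 0.91 (adjusted p = 0.311 and 0.27). The 18S 5' control read 59558 on wild-type array 2 and between 1621 and 6829 on the others.

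Sterol load, which lowers cholesterol synthesis genes, might raise LXR targets. The list mean differed by 0.11 (95% interval -0.23 to 0.44), which reaches past the 0.3 set beforehand and decides nothing. If SREBP activity as a whole were lower, fatty acid targets of SREBP1 might be lower by over 0.5. Their mean differed by -0.0726 (-0.82 to 0.68), also undecided. Of these targets only Gpam was lower by over 0.5 (-0.53), and Scd1 had the largest standard error (0.94). Collection at different times of day might move both gene groups. The contrast of evening-phase over opposite-phase clock genes differed by -0.21 (-0.62 to 0.19), an interval that reaches beyond 0.5 and leaves this open.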
